A study of Bos taurus with 8 samples.

How the data were processed

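RNA was measured in 8 libraries of bovine trophectoderm outgrowths, cultures grown from the outer cell layer of the embryo. Each outgrowth came from an individual in vitro produced embryo that had hatched, was plated on collagen IV on day 10 and was collected on day 35 (n = 4) or day 41 (n = 4). Total RNA was extracted with Trizol and sequenced on an Illumina instrument, per the labels. The submitters' processing notes name FastQC, HISAT2, featureCounts, edgeR and the genome build ARS-UCD1.2, without versions. The deposited table holds RPKM (reads per kilobase of exon over a scaled library size) computed by the authors for each library, and the exon length of each gene. It also holds the authors' own comparison of the days, with log2 fold changes and mean log2 counts per gene as deposited, a score per gene that is the likelihood ratio statistic of the authors' test, and the p-values and FDR the authors computed from it. Gene symbols and coordinates were taken from the same table, and 2035 of its 14970 genes have no symbol. EOMES, POU5F1, NANOG, SOX2, H19 and XIST were not analysed here.

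RPKM multiplied by exon length gave whole multiples of 1 step per library, within 0.01 of a whole number for 100% of values, and the reads behind each value were recovered from those steps. The recovered reads came to 106402848 to 158034430 per library, so 0.5 RPKM in a gene with 1 kilobase of exon stood for 55.4 to 79.3 reads. The scale factors behind the authors' RPKM were recovered in the same way and lay between 0.897 and 1.04. These reads are PCR products without molecular identifiers, so spread was taken from the outgrowths and not from counting error. Families with many near-identical copies, such as the pregnancy-associated glycoproteins, interferon tau, the prolactin-related proteins and the Kunitz-domain proteins, may share reads between copies, and the values of their single members are uncertain to that extent.

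The days were compared with limma 3.58.1 in R 4.3.3, by the limma-trend test on log2(RPKM + 1) with no covariate, over 12582 genes that reached 0.5 RPKM in at least 4 libraries. The adjusted p is that of Benjamini and Hochberg, with a threshold of 0.05, and all tests were two-sided. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes with low values. The groups, the test for normalized values, its threshold, the gene lists, the rule for naming genes and most of the alternatives were fixed before the data were examined. A count test had been planned for a table of counts, with camera and library scores on library-scaled counts. Because the table holds RPKM, those steps used log2(RPKM + 1). The filter was set after the value ranges and the number of genes past the authors' threshold had been seen and before the test was run. The libraries are called A to D (day 35) and E to H (day 41), in the column order of the table.

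The lists fixed in advance numbered 31 and held 715 distinct symbols. Of these, 604 matched a gene with values, and not all of the 604 reached the filter of the test. Lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, adjusted over 30 lists. An estimated correlation per list and fry, with statmod 1.5.0 present, were alternatives. A library score was the mean log2(RPKM + 1) of a list's tested members, compared between the days with an exact permutation test of 70 assignments, whose smallest possible p is 0.0286. The lists covered trophoblast transcription factors, keratins and junctions, interferon tau and Kunitz-domain proteins, pregnancy-associated glycoproteins, placental lactogen and prolactin-related proteins, and syncytin-type and binucleate cell genes. Others covered steroid, prostaglandin and cholesterol synthesis, lipid storage, pluripotency, hypoblast, mesoderm and stroma, immune cells, cumulus cells, epithelial-mesenchymal transition, S phase, G2 and mitosis, cell-cycle inhibitors, p53 targets and interferon-stimulated genes. The rest covered the unfolded protein and integrated stress response, heat shock, immediate early genes, glycolysis, hypoxia, mitochondrially encoded genes, imprinted genes, nutrient transporters, extracellular matrix receptors and growth factor signalling.

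The rule named the 8 genes with the largest change and the 5 with the smallest p in each direction, up to 4 members with the smallest p of each list described, a fixed set of markers and the 10 most abundant genes. Fewer than 5 genes passed in each direction, so the smallest unadjusted p was used for the first and second parts, as the rule provides. Some genes that the rule allowed were left out for length.

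The alternatives were median-of-ratios factors, upper-quartile factors, library totals, other filters and pseudocounts of 0.1 and 0.5. They also included leaving out the 20 most abundant genes, limma-voom on the recovered reads with and without sample quality weights, a robust prior, array weights, other thresholds, and leaving out each library in turn. On simulated data with 4 libraries per group, built for the comparison of day 41 with day 35, limma-trend recovered 62.9% of 97 genes changed 2-fold and 91.9% of 99 genes changed 4-fold, with 5 unchanged genes called among 12411 genes. The fit with sample quality weights recovered 57.0% of 100 genes changed 2-fold and 92.0% of 100 genes changed 4-fold, with 5 unchanged genes called among 12582. In the same simulation camera gave an adjusted p of 4.44e-23 for the shifted list and called 0 of 30 unshifted lists. Genes were drawn independently of each other and no library was made to stand apart. The simulation therefore cannot show how camera or the weights behave with correlated lists or an outlying library. In the data the estimated correlation within a list was 0.638 for G2 and mitosis and 0.927 for the placental lactogen list. Figures were drawn with matplotlib 3.10.9.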

Results

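Gene expression was measured by RNA sequencing in 8 bovine trophectoderm outgrowths, 4 collected on day 35 (libraries A to D) and 4 on day 41 (libraries E to H). The series concerns an in vitro model of trophectoderm differentiation, and the comparison of the days asks which genes differ after 6 more days of culture. The reads recovered from the deposited values ranged from 106402848 to 144658052 per library on day 35 and from 119797973 to 158034430 on day 41 (exact permutation p = 0.457). Values are RPKM scaled by the authors, given as mean ± SD with n = 4 per day unless stated. Coordinates are on ARS-UCD1.2.

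Outgrowths of both days expressed trophoblast markers at high levels. The epithelial keratins KRT8 and KRT18 reached 2537 ± 269 and 1150 ± 193 RPKM on day 35, and 1984 ± 213 and 878 ± 132 RPKM on day 41. The trophoblast transcription factors GATA2, GATA3 and TFAP2C stood at 112 ± 13.8, 90.1 ± 10.7 and 67.2 ± 7.53 RPKM on day 35, against 94.0 ± 9.78, 93.8 ± 9.19 and 62.6 ± 4.00 RPKM on day 41. CDX2, a regulator of early trophectoderm, was far lower, at 8.66 ± 1.10 and 6.95 ± 2.09 RPKM. ELF5 lay at 0.470 ± 0.142 and 0.228 ± 0.0621 RPKM, below the filter of the test. CDH1, the epithelial cadherin, was at 321 ± 9.09 RPKM on day 35 and 321 ± 35.6 RPKM on day 41. PPARG, a regulator of lipid metabolism, was at 13.7 ± 3.23 and 17.5 ± 1.66 RPKM. None of the tested markers in this paragraph passed the test between the days.

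The 10 most abundant genes were the mitochondrial COX1, COX2, COX3 and ATP6, the actins ACTB and ACTG1, the actin-binding TMSB10, the secreted protein gene SSLP1, and ENSBTAG00000045630 and ENSBTAG00000053661, which have no symbol. SSLP1 stood at 8167 ± 1701 RPKM on day 35 and 8167 ± 1031 RPKM on day 41. PTGS2, a prostaglandin synthase, was at 564 ± 173 and 495 ± 129 RPKM.

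**Figure D1:**
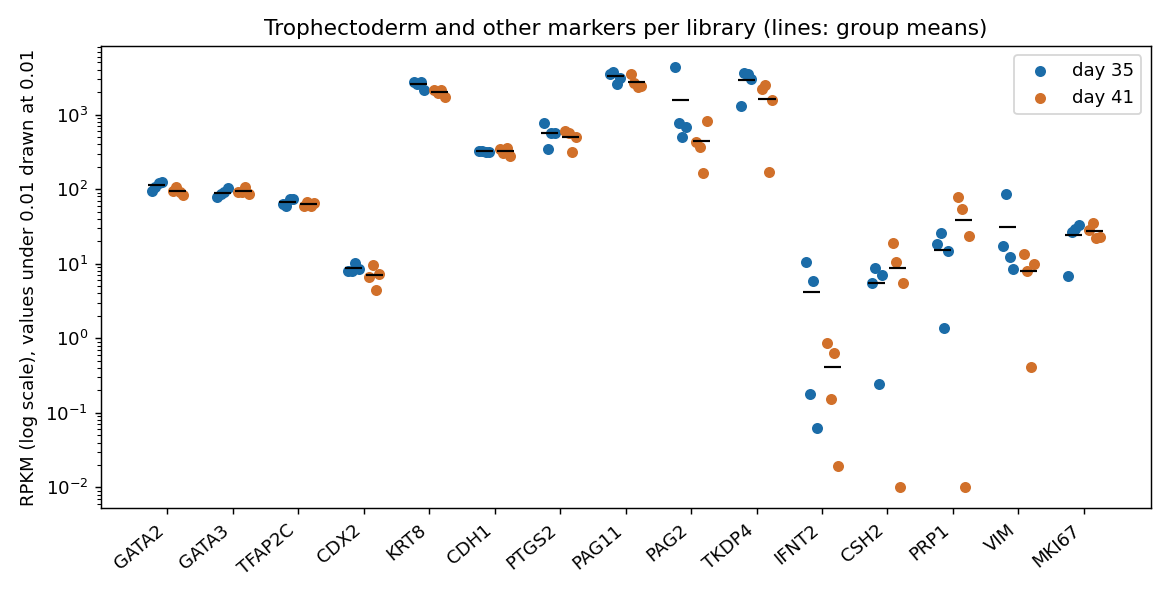
RPKM (log axis) of trophoblast, secreted product and other cell type markers in each library, with points for libraries, bars for the mean of each day (n = 4) and values of 0 drawn at the axis floor. KRT8 lies between 1700 and 2748 RPKM in the 8 libraries, while IFNT2 and VIM spread widely between outgrowths of 1 day.

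Markers of other embryonic lineages varied between outgrowths, and some were high in single libraries. The hypoblast regulators GATA4, GATA6 and SOX17 were at 0.201 ± 0.171, 4.15 ± 1.69 and 1.38 ± 0.449 RPKM on day 35 and at 0.0428 ± 0.0287, 2.42 ± 1.03 and 1.09 ± 0.916 RPKM on day 41. VIM, an intermediate filament of mesenchymal cells, ranged from 0.409 RPKM in library G to 86.4 RPKM in library B. IGF2, an imprinted growth factor, was at 24.7 ± 46.3 RPKM on day 35, where library B alone had 94.1 RPKM, and at 4.09 ± 5.10 RPKM on day 41. Without library B its log2 fold change turned from -0.85 to 0.51. The cumulus and granulosa list had a median of 0.312 RPKM over its 7 analysed members, of which 2 could be tested, so it was not tested as a list.

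Library A stood apart from the other 7. Its mean correlation with them was 0.954, against 0.966 to 0.976 for the others, and it alone lay at -52.5 on the first principal component, which held 33.9% of the variance. Ribosomal protein genes took 9.28% of its reads, against 5.13% to 6.49% elsewhere. MKI67, a proliferation marker, was at 6.77 RPKM in library A, and at 24.0 ± 11.9 RPKM over the 4 day 35 libraries against 27.4 ± 6.09 RPKM on day 41. The second component, with 20% of the variance, separated the days (exact permutation p = 0.0286, the smallest the design allows).

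**Figure D2:**
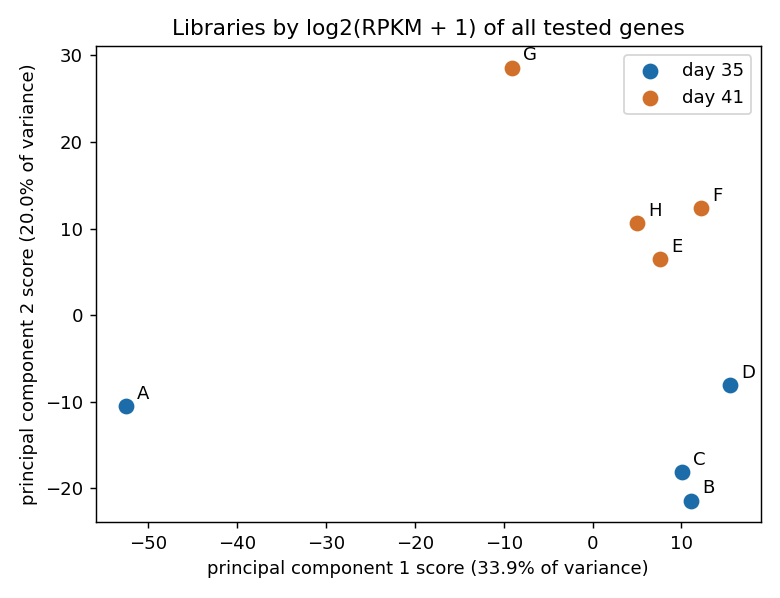
First and second principal components of log2(RPKM + 1) over the tested genes (axes in component units with the percent of variance), with 1 lettered point per library, coloured by day. Library A lies alone at -52.5 on the first component, and the days separate on the second.

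Between the days 6 genes changed by limma-trend with equal weights, 4 higher and 2 lower on day 41. With libraries weighted by quality, limma-voom called 372 genes higher and 280 lower, and limma-trend with array weights 592 and 452, with the 6 genes among them in both fits. FGFR4 (ENSBTAG00000010543, chromosome 7, 38575410 to 38586456), a fibroblast growth factor receptor, rose from 0.535 ± 0.0582 to 2.25 ± 0.171 RPKM (log2 fold change 1.08, SE 0.09, adjusted p = 0.0119). ST3GAL4 (ENSBTAG00000016506, chromosome 29, 29698724 to 29750191), which adds sialic acid to glycans, rose from 13.9 ± 1.25 to 35.7 ± 6.20 RPKM (1.29, SE 0.13, adjusted p = 0.0171). HSD17B7 (ENSBTAG00000005976, chromosome 3, 6634642 to 6664654), an enzyme of cholesterol and oestrogen synthesis, rose from 25.2 ± 3.06 to 52.5 ± 7.60 RPKM (1.03, SE 0.13, adjusted p = 0.0487). ADM2 (ENSBTAG00000054072, chromosome 5, 119789095 to 119793455), a peptide hormone of the adrenomedullin family, fell from 30.6 ± 1.60 to 9.47 ± 2.57 RPKM (-1.63, SE 0.19, adjusted p = 0.0345). CERS3 (ENSBTAG00000006987, chromosome 21, 6079335 to 6238773), a ceramide synthase, fell from 3.54 ± 0.397 to 0.917 ± 0.329 RPKM (-1.25, SE 0.14, adjusted p = 0.0345). The remaining gene, ENSBTAG00000042837 (chromosome 27, 19186465 to 19186541), has no symbol and an exon length of 77 bases, and rose from 9.59 ± 0.194 to 18.3 ± 0.990 RPKM (0.86, SE 0.08, adjusted p = 0.0119). It had only 1176 reads over all 8 libraries, so its small SD may be a chance result. Its FDR in the authors' own comparison was 0.374. In each of the 6 genes all 4 libraries of one day lay above all 4 of the other.

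Other genes with the smallest unadjusted p did not pass the threshold. ACSL4, which activates long-chain fatty acids, was at 18.3 ± 4.71 and 39.9 ± 1.73 RPKM (adjusted p = 0.0792), and ACSS2, which makes acetyl-CoA from acetate, at 12.9 ± 1.65 and 23.2 ± 2.02 RPKM (adjusted p = 0.0792). LPIN1, a phosphatidate phosphatase, was at 2.23 ± 0.759 and 6.11 ± 1.19 RPKM, and NADK2 and PRKD3 had the same adjusted p of 0.113. ABCG2, an efflux transporter, was at 58.5 ± 4.81 and 30.4 ± 4.99 RPKM (adjusted p = 0.0675), and GPR83 at 9.27 ± 1.65 and 4.6 ± 0.151 RPKM (adjusted p = 0.0855). ORAI1, SDF2L1 and RBM3 shared an adjusted p of 0.0938 with log2 fold changes of -0.71, -0.74 and -0.69, and MORN3 had an adjusted p of 0.105. In all, 1474 genes had an unadjusted p under 0.05, 742 higher and 732 lower, where chance gives 629. The days did not overlap in 1032 genes, or 8.20%, where chance gives 2.86%. These chance values are averages. Genes vary together, and the spread of these counts over other splits of the libraries was not computed, so the excess does not exclude chance. The fold changes held whichever library was left out, from 1.06 to 1.12 for FGFR4, 1.18 to 1.36 for ST3GAL4 and -1.72 to -1.43 for ADM2, but the calls did not: limma-trend called 0 genes without B, C, D, E or F (1040, 1125, 1705, 1051 and 1150 genes at an unadjusted p under 0.05), and 25 higher and 18 lower without A. Without G, HSD17B7, ADM2 and CERS3 lost their calls, and without H, HSD17B7 and CERS3 did.

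**Figure D3:**
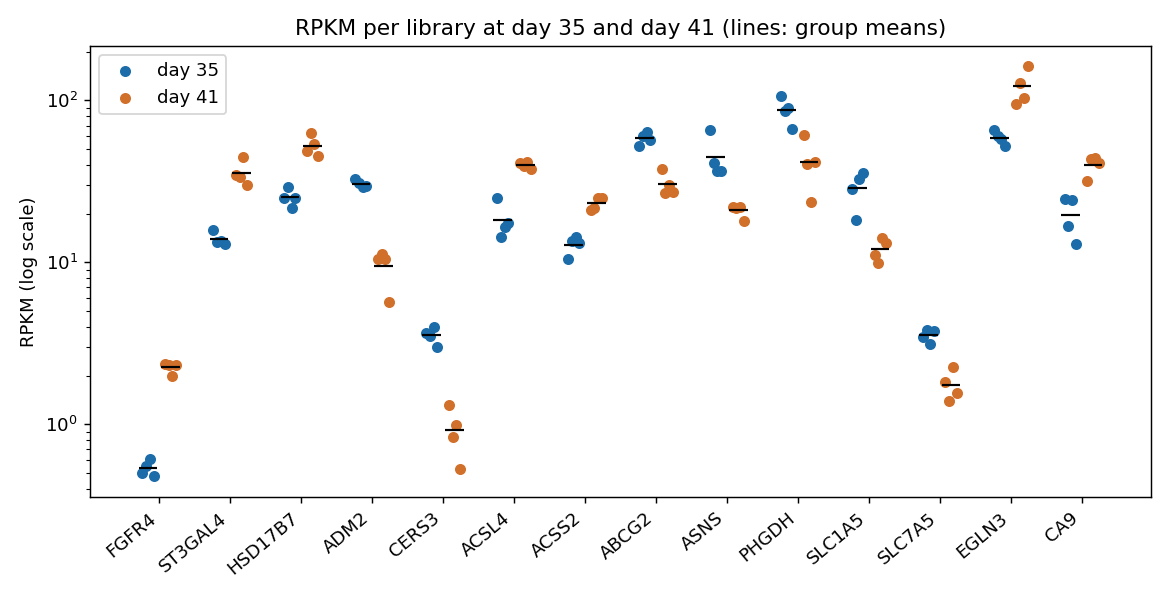
RPKM (log axis) in each library of the genes with a symbol that passed the test between the days, and of chosen genes that did not pass. Points are libraries and bars the mean of each day (n = 4). The 4 day 41 values of FGFR4 lie above all 4 day 35 values, and those of ADM2 below.

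The authors' own comparison in the deposited table, a likelihood ratio test, has 263 genes with an FDR under 0.05, 101 higher and 162 lower on day 41. Of these, 222 were tested here, all 222 had the same sign in limma-trend, 202 had an unadjusted p under 0.05 and 5 passed both tests. Both comparisons used the same 8 libraries, so the shared signs and small p-values are not independent evidence. In that table FGFR4 has a log2 fold change of 2.07 (FDR 1.01e-06), ST3GAL4 of 1.34 (FDR 1.87e-13) and ADM2 of -1.61 (FDR 2.56e-15). The ratio of mean RPKM of FGFR4 was 4.21 and its log2 fold change was 1.89 with a pseudocount of 0.1, so the lower value of 1.08 above goes with the 1 added to low RPKM. CERS3 likewise had -1.95 in the deposited table and -1.89 with a pseudocount of 0.1, against -1.25 above. ACSL4 has 1.21 (FDR 1.55e-09), and ENSBTAG00000042837 has an FDR of 0.374.

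Of the 26 genes of the unfolded protein and integrated stress response, 22 had lower values on day 41 and 4 higher (camera adjusted p = 1.82e-08, but adjusted p = 0.477 with an estimated correlation). None passed over all genes and 11 were lower when adjusted over the list alone. Here and below, counts over all genes are from limma-trend with equal weights. In limma-voom with quality weights 6 members were lower over all genes and 0 higher, and 7 were lower by the authors' FDR. ASNS, asparagine synthetase, was at 45.0 ± 14.1 and 21 ± 1.96 RPKM, PHGDH, the first enzyme of serine synthesis, at 87.3 ± 16.7 and 41.8 ± 15.3 RPKM, SDF2L1, an endoplasmic reticulum protein, at 15.8 ± 1.14 and 9.07 ± 1.23 RPKM, and DDIT4, an mTOR inhibitor, at 32.5 ± 3.59 and 19.1 ± 4.76 RPKM. The list's score was highest in library A, at 6.23, and without A the mean log2 fold change of its members was -0.30 in place of -0.45. Of 14 immediate early genes, 12 had lower values and 1 was lower when adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.00115, and adjusted p = 0.499 with an estimated correlation). JUN was at 72.6 ± 4.28 and 52.5 ± 2.04 RPKM, FOSL1 at 8.33 ± 2.46 and 4.76 ± 1.16 RPKM, MYC at 20.5 ± 8.58 and 11.5 ± 1.53 RPKM, and IER3 at 158 ± 61.0 and 94.4 ± 10.4 RPKM. Library A held the highest score of this list too, at 5.53, with MYC at 33.1 RPKM and IER3 at 248 RPKM, and without A the mean log2 fold change was -0.16 in place of -0.33.

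Of 21 amino acid and nutrient transporters, 12 had lower and 9 higher values, and 4 were lower when adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.0165, and adjusted p = 0.477 with an estimated correlation). The neutral amino acid transporter SLC1A5 was at 28.9 ± 7.69 and 12.1 ± 1.91 RPKM, SLC7A5 at 3.54 ± 0.318 and 1.76 ± 0.376 RPKM, SLC1A4 at 7.45 ± 1.59 and 3.54 ± 1.38 RPKM, and SLC7A11, a cystine transporter, at 0.722 ± 0.250 and 0.174 ± 0.0653 RPKM. The call was lost without D (adjusted p = 0.0674) and without G (0.0522). Of 24 p53 targets, 16 had lower values, and 1 of them, the cell-cycle inhibitor CDKN1A, was lower when adjusted over the list alone, at 57.9 ± 7.14 and 38.4 ± 4.41 RPKM, with 0 over all genes (camera adjusted p = 0.0379, and adjusted p = 0.477 with an estimated correlation). That call was lost without C (adjusted p = 0.108), D (0.185) and F (0.122).

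Of 10 mesoderm and stromal genes, 8 had lower and 2 higher values. Adjusted over the list alone, 3 were lower and 1 higher, with 0 over all genes (camera adjusted p = 0.0175, and adjusted p = 0.477 with an estimated correlation). The contractile genes ACTA2 and MYL9 were at 7.93 ± 6.80 and 248 ± 55.8 RPKM on day 35 and at 1.27 ± 1.03 and 155 ± 29.1 RPKM on day 41, and MESP1, a mesoderm regulator, was at 1.33 ± 0.170 and 0.646 ± 0.236 RPKM. COL5A1, a fibrillar collagen, went the other way, at 4.34 ± 2.86 and 23.7 ± 18.2 RPKM. Library F had 50.6 RPKM of COL5A1, against 12.25 to 19.1 RPKM in the other day 41 libraries. Library B had 17.8 RPKM of ACTA2, against 3.19 to 7.06 RPKM in the other day 35 libraries. Library B had the highest score of this list, and the call was lost without A (adjusted p = 0.0583), B (0.0807) and G (0.0769).

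Of 24 genes of cholesterol synthesis, 21 had higher values on day 41 (camera adjusted p = 6.73e-06, but adjusted p = 0.477 with an estimated correlation). Of these, 1 passed over all genes (HSD17B7) and 4 were higher when adjusted over the list alone. DHCR7, the last enzyme of one route to cholesterol, was at 74.3 ± 9.47 and 104 ± 4.59 RPKM, CYP51A1 at 73.8 ± 5.79 and 91.6 ± 2.18 RPKM, and INSIG1, a sterol sensor, at 26.9 ± 2.12 and 35.7 ± 4.86 RPKM. All 13 mitochondrially encoded genes had higher values, and 0 passed over all genes or when adjusted over the list alone (camera adjusted p = 0.0126, and adjusted p = 0.503 with an estimated correlation). ND5 was at 761 ± 140 and 1014 ± 66.7 RPKM and ND4L at 1057 ± 231 and 1424 ± 109 RPKM, and the call was lost without B (adjusted p = 0.0555) and D (0.0817).

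Of 32 genes of G2 and mitosis, 30 had higher values on day 41, and 0 passed over all genes or when adjusted over the list alone (camera adjusted p = 9.35e-05, and adjusted p = 0.616 with an estimated correlation). PTTG1, which restrains the separation of sister chromatids, was at 35.3 ± 2.66 and 45.4 ± 2.40 RPKM, and KIF23, a cytokinesis motor, at 32.3 ± 3.78 and 41.6 ± 1.67 RPKM. The list's score was lowest in library A and the call was lost without it (adjusted p = 0.243), with a mean log2 fold change of 0.05 in place of 0.20. Of 23 genes of the hypoxia response, 18 had higher values. Adjusted over the list alone, 2 were higher and 2 lower, with 0 over all genes (camera adjusted p = 0.0341, and adjusted p = 0.499 with an estimated correlation). EGLN3, a prolyl hydroxylase, was at 58.9 ± 5.72 and 122 ± 30.3 RPKM, CA9, a carbonic anhydrase, at 19.7 ± 5.84 and 40.2 ± 5.67 RPKM, and ANKRD37 at 5.71 ± 0.926 and 3.11 ± 0.985 RPKM, while DDIT4 is given above. The call was lost without A (adjusted p = 0.146), B (0.117) and E (0.105).

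**Figure D4:**
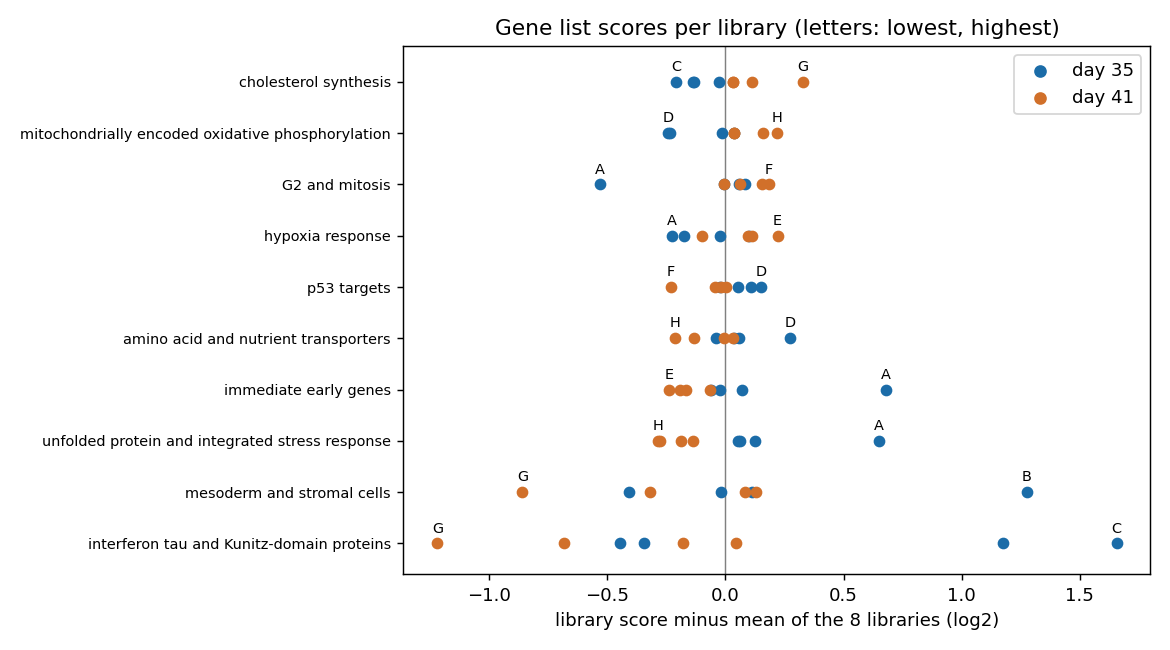
Score of each gene list past the threshold of camera in each library, as the mean log2(RPKM + 1) of its members minus the mean over the 8 libraries, with points for libraries and letters for the lowest and highest. Cholesterol synthesis scores are higher in all 4 day 41 libraries than in any day 35 library, while library A lies at the edge of the stress response and mitosis lists.

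Some products that the trophoblast secretes varied widely between outgrowths of 1 day, among them PAG2, IFNT and PRP1. The pregnancy-associated glycoprotein PAG11 was at 3259 ± 510 and 2737 ± 538 RPKM, and PAG8 at 695 ± 140 and 338 ± 139 RPKM. PAG8 had an adjusted p of 0.236 by limma-trend and an FDR of 0.00381 in the authors' comparison. PAG2 was at 1576 ± 1853 RPKM on day 35, with 4349 RPKM in library A, and at 441 ± 271 RPKM on day 41. The list had 12 of 16 members with higher values and an adjusted p of 0.884. The 4 with lower values, PAG2, PAG8, PAG11 and PAG12, were the 4 members above 10 RPKM. The direction of the list by camera turned to lower without A, C, E, F or H, and it was higher with an adjusted p of 0.00956 without G. All 7 members of the interferon tau and Kunitz-domain list had lower values on day 41, and 0 passed over all genes or when adjusted over the list alone (camera adjusted p = 0.0341, and adjusted p = 0.477 with an estimated correlation). IFNT was at 12.7 ± 13.9 and 3.06 ± 1.67 RPKM, IFNT2 at 4.16 ± 5.02 and 0.418 ± 0.399 RPKM, and TKDP4 at 2869 ± 1065 and 1603 ± 1027 RPKM. The log2 fold change of IFNT turned from -0.79 to 0.33 with unweighted limma-voom without library A. The call of the list was lost without A (adjusted p = 0.0767), C (0.144) and G (0.161). The placental lactogen CSH2 was at 5.44 ± 3.72 and 8.75 ± 8.05 RPKM, and the prolactin-related PRP1 at 15.1 ± 10.3 and 38.9 ± 34.4 RPKM, with 0 RPKM of both in library G. All 9 members of that list had higher values on day 41 by limma-trend, but CSH2 and PRP1 turned to lower with limma-voom, at log2 fold changes of -0.93 and -0.87, with a pseudocount of 0.1, at -0.032 and -0.027, without library C, at -0.37 and -0.17, and without E, at -0.26 and -0.11. The list's adjusted p was 0.252, against 4.96e-05 without library G. With an estimated correlation the adjusted p without G was 0.503 for this list and for the glycoproteins.

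The other lists did not pass the threshold of camera. The adjusted p was 0.0907 for syncytin-type and binucleate cell genes, 0.0938 for trophoblast transcription factors, 0.0938 for keratins and junctions, and 0.0997 for cell-cycle inhibitors and senescence, where CDKN1C was at 75.1 ± 63.0 and 59.4 ± 35.4 RPKM. It was 0.136 for steroid synthesis, 0.252 for hypoblast and yolk sac endoderm, 0.252 for S phase, 0.442 for heat shock, 0.497 for prostaglandin synthesis, 0.497 for epithelial-mesenchymal transition and 0.497 for glycolysis. It was 0.531 for interferon-stimulated genes, 0.589 for imprinted genes, 0.626 for lipid uptake and storage, 0.830 for extracellular matrix receptors, 0.884 for pluripotency, 0.957 for immune cells and 0.957 for growth factor signalling. Within lipid storage, 2 genes were higher (LPIN1 and SCD) and 2 lower (AGPAT2 and CPT1A) when adjusted over the list alone, with 0 over all genes. Adjusted over the list alone, HSD17B12 was higher among steroid synthesis genes, SLC1A5 lower among syncytin-type genes, CDKN1A lower among cell-cycle inhibitors, CD14 higher and FCER1G lower among immune genes, and FGFR4 higher among signalling genes, of which FGFR4 alone passed over all genes. CD14, a monocyte receptor, was at 8.58 ± 0.699 and 13.1 ± 1.63 RPKM. Single libraries moved several of these lists past the threshold at the preset correlation, and with an estimated correlation camera called 0 lists without any one library (lowest adjusted p = 0.375). Without A, steroid synthesis was past the threshold higher (adjusted p = 0.0329), and hypoblast (0.0329) and syncytin-type genes (0.0403) lower, with an adjusted p of 0.375, 0.64 and 0.375 with an estimated correlation. Without G, the lactogen list (4.96e-05) and the pregnancy-associated glycoproteins (0.00956) were past it higher and interferon-stimulated genes (0.0231) lower, as were interferon-stimulated genes without B (0.0472). S phase passed higher without C (0.0248) and H (0.0474), while trophoblast transcription factors (0.0408) and keratins (0.0491) passed lower without F, syncytin-type genes (0.0424) without E and cell-cycle inhibitors (0.041) without H. Library scores separated the days in 4 lists at the smallest exact p of 0.0286 (cholesterol synthesis, stress response, immediate early and mitochondrially encoded genes), and 0 lists passed after adjustment (smallest adjusted p = 0.214, exact permutation test).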

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

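The tests of sequencing depth, of the scale factor, of library A alone for the stress and sterol genes, and of the relation of the lactogen and glycoprotein families were chosen only after the result was seen. The values given against those of the other 3 outgrowths of the day lie far from them by Dixon's criterion at the 95% level. The stress and sterol pattern between the days and the lactogen score of library G were not flagged by that criterion. Of 262 groups of 4 looked at, 19 met it where chance gives 13.1, and 9 of the 19 were in library A, 5 in G, 3 in H, 1 in C and 1 in F.

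Library A differed from B, C and D in growth, stress and translation genes. The score of G2 and mitosis was 4.39 in A against 4.91 to 5.00, MKI67 was at 6.77 RPKM against 26.4 to 33.3, the score of the unfolded protein and integrated stress response was 6.23 against 5.63 to 5.70, ribosomal protein genes took 9.28% of reads against 5.13% to 5.72%, and the first principal component was -52.5 against 10.1 to 15.5. Over all tested genes the deviation of A from the other libraries went with exon length (Spearman rho = -0.397), with shorter genes higher. Gene length bias is argued against as the whole cause, since after a length trend was removed the median deviation of G2 and mitosis genes was still -0.57 and that of ribosomal protein genes 0.61 on the log2 scale. The latter was 0.85 before, so part of it went with length. Mitosis genes, at a median of 2669.5 bases against 2329.5 over all genes, were moved little by the correction. Lower depth is argued against because 3 other libraries had fewer reads, and the scale factor because ribosomal protein genes deviated by 0.85 and mitosis genes by -0.58, in opposite directions. A slower-growing or stressed outgrowth, partly degraded RNA and a mislabelled sample may each account for the rest, and the design gives no group that would test them.

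The stress list tended lower on day 41, with 22 of 26 members lower, and cholesterol synthesis higher, with 21 of 24 members higher. The amino acid transporters were divided, with 12 of 21 members lower and 9 higher. By camera with an estimated correlation the adjusted p of each list was 0.477. Chance cannot be excluded for the number of lists past the threshold, since 15 of 35 splits of the libraries gave as many as the real 10. Library A alone is argued against as the cause, since without it the mean log2 fold change of the stress list was -0.30 and that of cholesterol synthesis 0.25. Gene length bias between the days is argued against as the whole cause, with means of -0.44 and 0.25 after a length trend was removed. Chance, time in culture, the state of the medium at collection and unrecorded batches of embryos or libraries stay open, because none of the last 3 was tested and each could follow the day.

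The placental lactogen and prolactin-related genes ranged from near 0 in libraries C and G to high values in others. The score was 0.448 in library C against 2.44 to 2.69 in the other day 35 libraries. Over the 6 libraries other than C and G, it followed the score of the pregnancy-associated glycoproteins (r = 0.870, exact permutation p = 0.0167; rho = 0.943, exact permutation p = 0.0167; 1 relation computed), and r was 0.728 without E and F, the libraries farthest from the median. Reads shared between copies stay open, because the glycoproteins are also a family of near-identical copies and the relation therefore excludes nothing. A different share of binucleate cells, which make members of both families, is a candidate explanation that was found on these data and was not tested. The glycoproteins did not all vary alike. In libraries C and G PAG20 was at 0.0245 and 0 RPKM, while PAG11 was at 2609 and 2363 RPKM.

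Other values were reported without a test of their cause. In library A the steroid synthesis score was 4.80 against 4.44 to 4.49. HSD17B12, a steroid and fatty acid enzyme, was at 75.4 RPKM in A against 61.0 to 62.2. PPARG was at 18.5 RPKM in A against 11.6 to 12.5. TKDP2 was at 0.165 RPKM in A against 2.03 to 2.46. In library G the imprinted gene score was 4.22 against 3.86 to 3.90. DDB2, a DNA repair gene, was at 11.3 RPKM in G against 8.38 to 8.67. ENSBTAG00000045630 was at 8980 RPKM in G against 6300 to 6650. FGFR4 was at 1.99 RPKM in G against 2.33 to 2.35. TKDP4 was at 169 RPKM in G against 1580 to 2489. In library H the epithelial-mesenchymal transition score was 5.13 against 4.39 to 4.49. ADM2 was at 5.66 RPKM in H against 10.5 to 11.2. ASNS was at 18 RPKM in H against 21.7 to 22.1. The scale factor of library F was 1.03 against 1.00 in the other 3 day 41 libraries.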

How the results depend on the processing

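The robust prior, the array weights, the weighted fit without library A, unweighted limma-voom without A, camera on the weighted fit and the estimated correlation without each library were chosen after the data were seen. Against 4 genes higher and 2 lower, limma-voom called 2 higher and 0 lower (1481 genes at an unadjusted p under 0.05). Without a filter or with a pseudocount of 0.1 limma-trend called 0 lower (1664 and 1465 genes). At an adjusted p under 0.1 there were 7 higher and 7 lower. With sample quality weights there were 372 and 280, with array weights 592 and 452, and with quality weights but without A 435 and 305. The quality weight of A was the lowest, at 0.133, but limma-voom without A called 11 higher and 6 lower when unweighted, against 740 in all when weighted, so within limma-voom the low weight of A alone does not account for the gain. The cause of the other changes was not tested. The 6 genes were among those called in each of these 3 weighted fits. Leaving out each library in turn gave 0 to 25 higher and 0 to 18 lower genes. Of 10 lists, 0 passed with an estimated correlation (1 list at an unadjusted p under 0.05), 0 with an estimated correlation without any one library and 0 with the directional test of fry, while 6 of the 10 were among 11 lists past its mixed test of change in either direction. By comparison 6 passed with camera on the weighted fit, which lost interferon tau and Kunitz-domain proteins, mesoderm, mitosis and hypoxia. Of 210 combinations of these 10 lists and settings, 89 kept the call, 121 lost it and 0 turned direction. No scaling moved the median log2 fold change by more than 0.0247.

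Across the 35 ways to split the 8 libraries 4 against 4, only the real split gave as many as 6 genes. That is the smallest share they allow, 1 of 35, but another split gave 5, so the margin is narrow and chance is not excluded. Chance is argued against at the same share, with a wider margin, for the 652 genes of the weighted fit (highest other 27). It cannot be excluded for the 10 lists, since 15 of 35 splits gave as many and the highest other gave 12. Without A, the 7 libraries have 35 splits of their own, 3 against 4, and for the 43 genes chance is argued against at 1 of those 35 (highest other 9).

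Of 1987 combinations of 91 named genes and settings, 1768 kept direction and side of the threshold, 53 lost a call, 116 gained one and 50 turned direction, in 11 genes of which none was called and whose cause was not tested. The log2 fold change of CDH1 was 0.023 with library totals, 0.027 with quality weights, 0.037 with array weights, 0.034 with quality weights without A, 0.0079 with unweighted limma-voom without A, and -0.060 to 0.062 leaving out each library. CDKN1C had 0.0055 with quality weights, 0.20 with quality weights without A, 0.38 with unweighted limma-voom without A, and -0.50 to 0.38. CSH2 had -0.032 with a pseudocount of 0.1, -0.93 with limma-voom, -0.62 with limma-voom without A, and -0.37 to 1.18. PRP1 had -0.027, -0.87 and -0.56 in the same settings, and -0.17 to 1.995. GATA3 had -0.0044 with quality weights without A, and -0.0053 to 0.13. IGF2 had -1.68 to 0.51. IFNT had 0.33 with unweighted limma-voom without A. MKI67 had -0.034 with quality weights, -0.029 with array weights, -0.10 with quality weights without A, -0.14 with limma-voom without A, and -0.14 to 0.58. PAG11 had 0.024 with array weights and 0.038 with quality weights without A. PTGS2 had 0.10, 0.12 and 0.066 in the 3 weighted fits, and -0.39 to 0.035. SSLP1 had -0.0037 with upper-quartile factors, -0.11, -0.12 and -0.12 in the 3 weighted fits, -0.075 with limma-voom without A, and -0.076 to 0.12. Marker levels were recomputed with library totals alone. All 24 means moved by no more than the SD over the 8 libraries of both days, which is a weak check for genes with a wide spread.

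No paired analysis was possible because the days share only outgrowth number 1 and the columns of the table carry no outgrowth numbers. For that reason leaving out outgrowth 1 of both days was not run. The planned DESeq2 test, the edgeR robust fit and svaseq were not run, because the deposited values are RPKM and the recovered reads were used with limma-voom only, and XIST as a covariate was not analysed here. How the calls depend on depth was not tested, and a gene at the filter with 1 kilobase of exon had 55.4 to 79.3 reads.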

Other observations

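The lists in this part, the test of the aminoacyl-tRNA synthetases and the genes named were chosen only after the result was seen, from genes with small unadjusted p, so their p-values are not independent evidence. Enzymes that load amino acids onto transfer RNA had mostly lower values on day 41 in the cytosol. Of 20 cytosolic aminoacyl-tRNA synthetases, 16 had lower values and 10 were lower when adjusted over the list alone, with 0 over all genes (camera adjusted p = 1.76e-07 over 6 lists, and adjusted p = 0.0857 with an estimated correlation). GARS1, for glycine, was at 122 and 71.1 RPKM, CARS1, for cysteine, at 50.9 and 29.4 RPKM, and MARS1, for methionine, at 26.2 and 17.6 RPKM (means, n = 4 each). The mitochondrial set had 11 members with higher and 6 with lower values (adjusted p = 0.627). The sets are not cleanly separate, since GARS1 and KARS1, counted as cytosolic, also encode the mitochondrial enzymes. Of 10 genes of serine and one-carbon synthesis, 8 had lower values and 6 were lower when adjusted over the list alone, with 0 over all genes (camera adjusted p = 4.1e-06, and adjusted p = 0.0153 with an estimated correlation), among them PSPH at 64.9 and 37.6 RPKM. Without library A the adjusted p was 6.67e-07 for the cytosolic synthetases and 0.000229 for serine and one-carbon synthesis.

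Genes of fatty acid activation and synthesis had mostly higher values on day 41. Of 19 members, 18 had higher values, and 6 were higher and 1 lower when adjusted over the list alone, with 0 over all genes (camera adjusted p = 2.02e-07, and adjusted p = 0.0438 with an estimated correlation; 1.29e-05 without library A). SREBF1, a regulator of lipid synthesis, was at 15 ± 2.10 and 22.8 ± 3.19 RPKM, ACLY, which makes cytosolic acetyl-CoA, at 51.1 ± 5.84 and 67.5 ± 3.96 RPKM, and SCD, a fatty acid desaturase, at 115 ± 35.1 and 198 ± 17 RPKM. The sialyltransferases, the family of ST3GAL4, had an adjusted p of 0.611, and the carbonic anhydrases, the family of CA9, of 0.627.

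Most cytosolic synthetase and serine genes, ASNS and 12 of 21 transporters had lower values on day 41. None passed over all genes by limma-trend with equal weights in all 8 libraries. With quality weights limma-voom called 7 synthetases, 4 serine genes and 4 transporters lower, and 1 transporter higher. By the authors' FDR 4 transporters were lower and 1 higher, and ASNS had an FDR of 1.63e-05. A candidate explanation is a weaker response to amino acid shortage on day 41, in which the transcription factor ATF4 acts on cytosolic but not mitochondrial synthetases. In a permutation of genes between the sets, the difference in mean log2 fold change of -0.33 had p = 0.00035. This is not evidence for the hypothesis, because the sets were picked after these genes had been seen to be lower and genes are not independent replicates, so the hypothesis stays untested. ATF4 itself was at 417 ± 108 and 248 ± 42.4 RPKM (adjusted p = 0.236).

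Library B had the highest values of some transcripts of other embryonic lineages, named after their values were seen. COL1A1, a fibrillar collagen, was at 76.4 RPKM in B and at most 13.6 RPKM elsewhere. AFP, a yolk sac protein, was at 95.4 RPKM in B and at most 59.6 RPKM elsewhere, and APOA1, an apolipoprotein, at 336 RPKM in B and at most 73.5 RPKM elsewhere.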
